A study of Homo sapiens with 6 samples.

How the data were processed

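Duodenal biopsies of 3 CVID patients and 3 controls were each hybridised to 1 Agilent whole human genome array, and groups and numbers were taken from the sample titles. The raw file name in the description of 1 control did not match its group, and the title was followed. Per the labels' protocols, 50 ng of total RNA was amplified and labelled with Cy5, and a common reference of normal full-thickness duodenum RNA with Cy3. All biopsies ran in the same dye orientation, so a dye effect is not balanced within a group, although it is common to both groups. Per the file headers, the deposited scanner files came from Agilent Feature Extraction 10.7.3.1 (also named in the submitters' processing notes) and hold 45015 spots per array. Per the file headers, the mean intensity and the local median background intensity of each spot and channel were not normalized, whereas the processed intensity had been background-subtracted and dye-normalized by the scanner software. The deposited LogRatio is the log10 of Cy5 over Cy3 processed signal, per the file headers. The authors' value table was taken as log2 of Cy5 over Cy3, per the series' design text. It correlated with LogRatio at 0.891 to 0.934 across probes, so its direction was that of Cy5 over Cy3. Its column medians were 0.0192, 0.0331 and 0.0370 for controls 1, 2 and 3, and 0.0144, 0.0209 and 0.0116 for CVID patients 1, 2 and 3. Its normalization and the filter behind its 16.8% to 28.8% of empty cells are not given in the sources used here.

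The main values were computed in R 4.3.3 with limma 3.58.1 and the data.table package, version 1.17.8. Mean and background intensities were corrected with normexp at an offset of 50, normalized by loess within each array with control spots at weight 0, and not normalized between arrays. Spots marked as population outliers (0.403% to 0.556% per array) were left out. Spots marked as non-uniform (25.5% to 36.2%) were kept, because they made up 69.9% to 93.2% of the Cy5 spots at or above the 90th percentile of an array. Signals 20 or more below their local background occurred at 36 spots of CVID patient 2, against at most 4 on any other array, and the local background of that array reached 65527 in Cy3. They drew the normexp background mean to -900 in Cy3 and -392 in Cy5, and the median absolute deviation of that array's log2 ratios to 0.031. The scanner software had marked the local background of all 36 as an outlier. For every spot so marked (2.10% to 2.73% per array), the array's median background of that channel therefore replaced the local one. The median absolute deviations were then 0.253 to 0.366. This repair was not part of the design as first written and was chosen after results without it had been seen; the closing section gives the counts without it and with such spots left out.

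Of 43376 non-control spots, repeated spots of 41000 probes were averaged. Probes were kept if well above background in Cy5 on at least 3 of the 6 arrays, and the kept probe with the highest mean intensity stood for a gene. In all, 26386 probes were named by RefSeq accession, 2399 by current symbol and 587 by an older symbol in a gene table of assembly GRCh38.p14; 9 older symbols pointing to another chromosome were not used, and 11628 probes kept the file's name. Probe coordinates are those of the hg19 scanner files; the arrays of scan 1 carry hg18 annotation. XIST, TSIX and 110 sex-linked probes in all were removed before testing, and genes that vary by deletion between people or lie on both sex chromosomes were tested but not named, which applies to 1 called gene. Of 157 genes named by the rule, 40 had several kept probes, and for 4 (APOA4, BCL11A, GGT1 and MOB3B) these differed in sign.

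Groups were compared with lmFit and eBayes, two-sided, with Benjamini-Hochberg adjustment over 18139 genes and a threshold of 0.05. Gene lists were tested with camera at a preset correlation of 0.01, adjusted over 36 lists with at least 5 genes tested, and with fry. Some 22 genes were in more than 1 list. The lists, tests and most alternatives were fixed in advance. Named genes were the 10 largest differences per direction among genes past the threshold without overlap between groups, filled up by smallest p. To these came up to 4 genes of smallest p per list, and GATA4, JCHAIN, MS4A1, CD3E and APOA4. Features known only by an accession, clone or probe identifier, or by an open reading frame symbol, were not named by the rule. Leaving genes on both sex chromosomes unnamed was decided after the results were seen, to protect donors. Some genes that the rule names, or that changed, are not reported here. A gene not well above background on any array of a group has only a bound there, written as at least N-fold, taken per channel after loess and Aquantile and open to dye bias. It is not given where it exceeds the fold of the log2 ratios themselves. On simulated data of 18139 genes, limma recovered 34%, 94%, 100% and 100% of 50 genes changed by 1, 2, 3 and 4 on the log2 scale, and 14 unchanged genes were called. A simulated list of 30 genes shifted together by 0.5 passed limma's camera test, and an unshifted one did not. Noise was drawn independently for each gene, without slide or scan effects. The simulations thus do not test the calls where genes vary together. In the data, the correlation estimated for the interferon gamma list was 0.49.

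The alternatives covered the background correction, offset 16, the normalization, the reference channel, the authors' table, filters, probe rules, array weights, robust eBayes, an adjusted p of 0.10, the replicate number or scan as a block, each array left out, and the list tests. Those added after seeing the data were the shared slide alone, slide as a random block, non-uniform spots left out and both treatments of marked backgrounds.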

Results

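Gene expression was measured in duodenal biopsies from 3 patients with common variable immunodeficiency (CVID), a primary disorder of antibody production, and from 3 controls, with 1 array per biopsy. The raw file name given for 1 control carries the abbreviation of the disease, so its label is in doubt, and it was kept as a control, as titled. The labels describe the controls as having other, unrelated pathology. Amplified RNA of each biopsy carried the dye Cy5 and was hybridised together with the same Cy3-labelled reference, commercial RNA of normal full-thickness duodenum. Every value is therefore a log2 ratio of biopsy over reference, and the reference cancels in the difference between patients and controls. Between 44.7% and 62.1% of the probes were well above background in Cy5 on an array, with the lowest shares, 45.5% and 44.7%, on controls 1 and 2. Against the full-thickness reference, smooth muscle genes were low in every biopsy (medians of -3.08 to -2.35), and brush border genes were high (0.84 to 2.04). Pearson correlations of the log2 ratios across genes were 0.801 to 0.857 among the patients, 0.734 to 0.812 among the controls and 0.623 to 0.765 between the groups.

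All 3 patients and control 3 were on the same slide and scanned together (scan 2), whereas controls 1 and 2 were on other slides of scan 1. The comparison within the shared slide thus sets 3 patients against 1 control, and its values are given beside those of all 6 arrays for the lists and for most genes named. Across genes, the log2 ratios of control 3 correlated at 0.734 and 0.762 with controls 1 and 2. With CVID patients 1, 2 and 3 they correlated at 0.744, 0.765 and 0.672. Control 3 was thus closest to a patient of the shared slide, and the ranges above do not separate group from slide. The number of arrays limits the precision, and p-values measure only the spread among these 6 biopsies.

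The single comparison of the design asks how the duodenal mucosa of CVID patients differs from that of controls. By limma's camera test, lists of interferon-induced, antigen-presentation, T cell and macrophage genes were higher in the patients and the list of plasma cell genes was lower. None of these list calls held with an estimated correlation (smallest adjusted p = 0.345 with an estimated correlation), and no gene of the macrophage list passed over all genes. Of 18139 genes tested with limma, 201 were higher and 16 lower in the patients at a Benjamini-Hochberg adjusted p of 0.05. UBD, an interferon-inducible ubiquitin-like protein (probe on chromosome 6, 29523477 to 29523536, hg19), showed a log2 difference of 5.21 ± 0.77 (SE, n = 3 against 3; limma adjusted p = 0.0292), or 37.1-fold. The macrophage elastase MMP12 (chromosome 11, 102733513 to 102733572) was higher by 3.01 ± 0.30 (limma adjusted p = 0.0120) and LCP1, the actin-bundling plastin of leukocytes, by 2.49 ± 0.23 (limma adjusted p = 0.0120). RNF182, CR1, a complement receptor, and SLAMF8, a receptor of myeloid cells, were higher by 3.09, 2.51 and 2.45, but the second probe of CR1 gave 0.67, and CR1 was called in 6 of 25 settings. Within the shared slide UBD, MMP12, LCP1, RNF182, CR1 and SLAMF8 had differences of 5.24, 3.53, 2.56, 3.65, 2.52 and 3.06. IGHA2, a constant region of the IgA heavy chain (chromosome 14, 106053276 to 106053335), was lower, with a difference of -2.38 ± 0.25 (limma adjusted p = 0.0120), while its 3 probes ranged from -2.38 to -0.19. Among the genes named by the rule, COLCA1, TMBIM1, the mitochondrial ND5 and DYNC2I2 followed with -1.59, -1.37, -1.35 and -1.26, and MOB3B with -1.15, although its probes disagreed in sign. Within the slide IGHA2 and these 5 had -1.91, -1.36, -1.70, -1.34, -0.94 and -0.94. C6orf141, outside the naming rule and singled out after its value was seen, was lower too (-1.37, -1.31 within the slide, limma adjusted p = 0.0282). ANKRD23, MSMB, TGFB3 and MYO18A, with differences of -1.66, -1.74, -1.05 and -0.91, did not overlap between the groups but were not past the threshold (limma adjusted p = 0.0540, 0.0546, 0.0544 and 0.0553; -2.26, -1.63, -1.31 and -0.81 within the slide). The second probe of MSMB gave -0.82.

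These counts changed with the arrays used. With scan as a block, and within the shared slide, which rest on the same contrast of the patients with control 3, limma called 0 genes in either direction at the adjusted threshold (1632 higher and 874 lower at an unadjusted p under 0.05 with the block, 1581 and 869 within the slide). Yet all 201 higher and all 15 listed lower genes kept at least 0.5 of their difference there. This is partly by construction, since 4 of the 6 arrays are reused and these genes differed without overlap between the groups. Over all genes tested, 76.3% kept their sign within the slide, and the differences correlated at 0.776 with those of all arrays. The lost calls thus neither show nor exclude that the slide carries them. Limma also called 0 without control 1 (1713 higher and 893 lower unadjusted), 0 without CVID patient 1 (1688 and 847) and 0 in the authors' value table (1676 and 1105) or with median centring in place of loess (1487 and 192). Counts fell to 25 higher and 2 lower without control 2, to 16 and 0 without CVID patient 3, and to 96 and 27 without CVID patient 2; they were 138 and 22 without control 3. The counts further rest on a repair of faulty local backgrounds, chosen after results without it had been seen. Without the repair 3 genes were higher and 0 lower (1311 and 935 unadjusted). The scanner software's own processed signals, which do not use that background step, gave 258 higher and 9 lower, and 93 of the 217 genes were called there too. Groups did not overlap for 4582 genes, 25.3% of those tested, against 10% for random groups of 3 and 3. Like CR1, other called genes passed in only part of the settings. LCP1 passed in 19 of 25, UBD in 13 of 25 and SLAMF8 in 8 of 25. Of the list genes given below, ZAP70 passed in 7 of 25, TAP1 in 6 of 26 and IDO1 in 4 of 24.

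**Figure D1:**
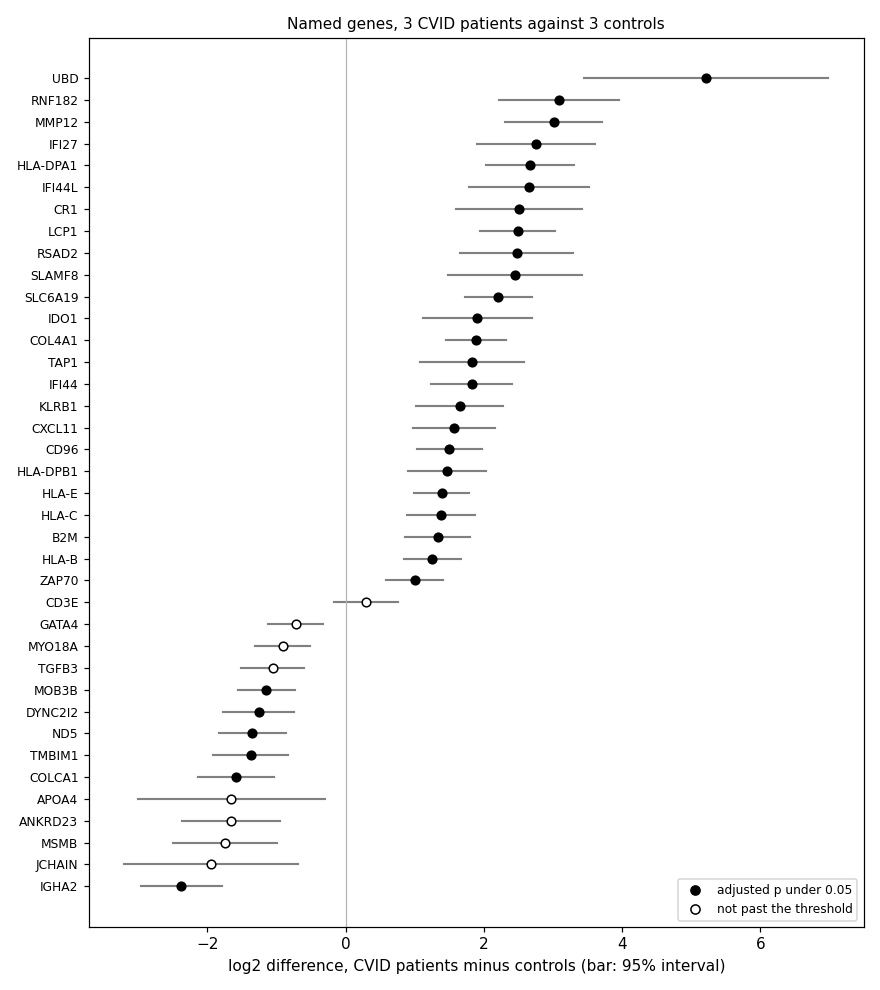
Log2 difference of CVID patients minus controls (x axis) for named genes (y axis), with 95% intervals from limma over 3 and 3 biopsies; filled points have an adjusted p under 0.05. UBD lies highest at 5.21 and IGHA2 lowest at -2.38.

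Of 36 gene lists fixed before the data were examined, 12 were higher and 9 lower in the patients by limma's camera test with a preset correlation of 0.01. None of these 21 calls held with a correlation estimated for each list, where the smallest adjusted p was 0.345. The directional test fry called 3 of them, MHC class I and class II presentation (adjusted p = 0.0273 for each) and antibody transport (adjusted p = 0.0364). Within the shared slide all 21 lists kept their direction and at least 0.5 of their median difference. That slide holds 1 control, whose spread is not measured, and its 4 arrays also enter the comparison of all 6. Without non-uniform spots, which leaves 5 T cell and 9 type I interferon genes, 4 of the 21 lists passed and 13 did not. The others had fewer than 5 genes left and were not tested there. Ranges given below as over settings are the lowest and highest median of a list among all alternatives.

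**Figure D2:**
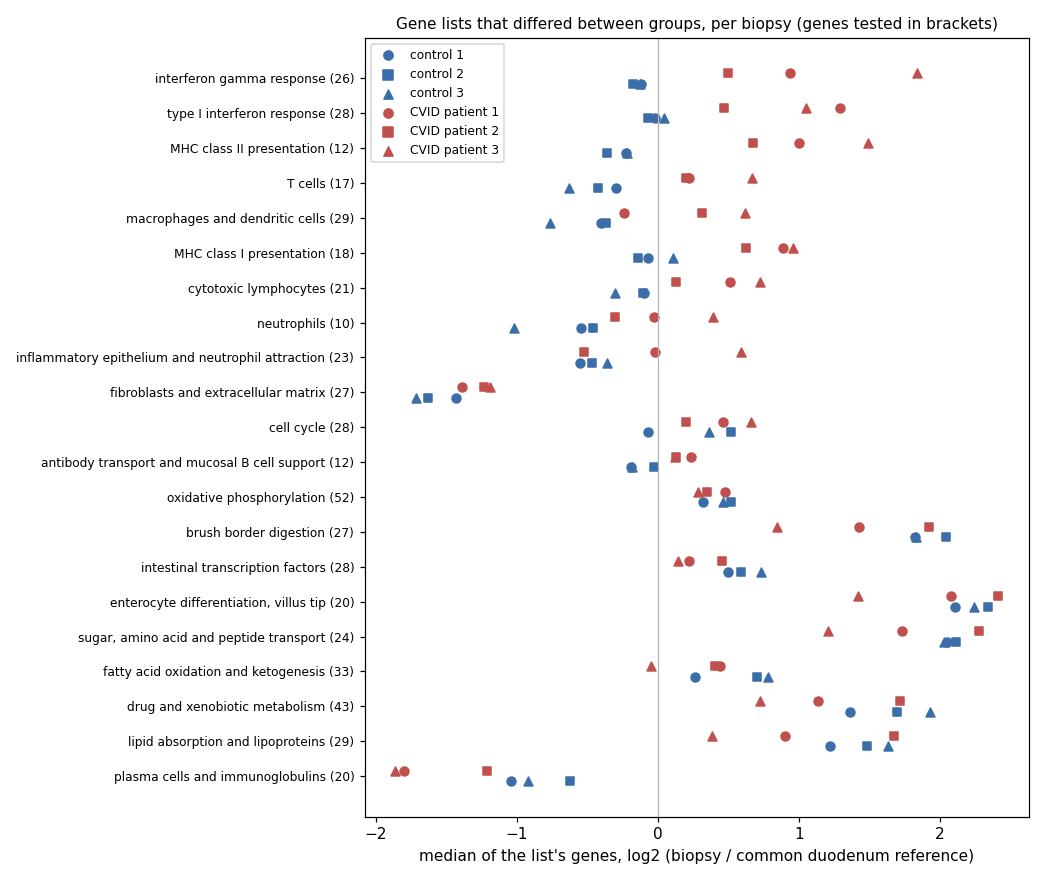
Median log2 ratio of biopsy over reference (x axis) of each gene list that passed the camera test (y axis, number of genes in brackets), with 1 point per biopsy, blue for controls and red for CVID patients. Interferon gamma response medians were -0.18 to -0.12 in the controls and 0.50 to 1.84 in the patients; for lipid absorption, CVID patient 2 at 1.67 lay with the controls at 1.22 to 1.63.

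Interferon-induced genes were higher as lists. Of 26 interferon gamma response genes, all 26 were above 0, with a median difference of 1.14 (1.32 within the slide, camera adjusted p = 3.5e-12, adjusted p = 0.379 with an estimated correlation). The median was 0.91 to 1.84 over settings, and 4 genes passed over all genes and 20 adjusted over the list alone. IDO1, which degrades tryptophan, was higher by 1.91 ± 0.34, and TAP1, which carries peptides to MHC class I, by 1.83 ± 0.33 (limma adjusted p = 0.0471 and 0.0482; 1.83 and 1.72 within the slide). The chemokine CXCL11 was not well above background on any control and was at least 2.08-fold higher in the patients (limma adjusted p = 0.0377). The chemokine CXCL9, at 2.97 ± 0.86 (3.74 within the slide), passed adjusted over the list alone. The type I interferon list had a median of 1.08 (0.83 within the slide, camera adjusted p = 8.5e-11, adjusted p = 0.345 with an estimated correlation), with 25 of 28 genes above 0. Over settings it was 0.44 to 1.32, lowest and not called without non-uniform spots. In that list 5 genes passed over all genes and 18 adjusted over the list alone. IFI27, IFI44L, RSAD2 and IFI44 were higher by 2.76, 2.65, 2.48 and 1.82 (limma adjusted p of 0.0231 to 0.0282), and by 2.80, 2.72, 2.38 and 1.92 within the slide; a second probe of RSAD2 gave 1.39.

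Antigen-presentation genes showed the same direction in nearly all members. In the MHC class II list all 12 genes were above 0, with a median of 1.08 (1.09 within the slide, camera adjusted p = 1.2e-08, adjusted p = 0.345 with an estimated correlation). HLA-DPA1 and HLA-DPB1, the chains of HLA-DP, rose by 2.67 ± 0.28 and 1.47 ± 0.24 (limma adjusted p = 0.0120 and 0.0385). Within the slide they had 2.67 and 1.62, and their second probes gave 1.88 and 2.56. In this list 10 genes passed adjusted over the list alone. In the MHC class I list 17 of 18 genes were above 0, with a median of 0.77 (0.71 within the slide, camera adjusted p = 1.2e-08, adjusted p = 0.345 with an estimated correlation). There 6 genes passed over all genes and 14 adjusted over the list alone, among them HLA-E (1.39 ± 0.17), HLA-C (1.38 ± 0.21), B2M (1.33 ± 0.20), the light chain shared by class I molecules, and HLA-B (1.26 ± 0.18). Within the slide these 4 had 1.29, 1.46, 1.02 and 1.21. The probes of HLA-E ranged from 0.81 to 1.53 and those of HLA-C from 0.93 to 1.38. HLA probes can hybridise with related HLA transcripts and match alleles unequally, so their values are uncertain; B2M and TAP1 do not share that limit.

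T cell and cytotoxic lymphocyte genes were higher in the patients. All 17 T cell genes were above 0, with a median of 0.98 (0.79 within the slide, camera adjusted p = 1.6e-07, adjusted p = 0.436 with an estimated correlation), and 2 passed over all genes and 10 adjusted over the list alone. The median was 0.29 to 1.54 over settings, lowest and not called without non-uniform spots, and 0.30 without the filter on dim probes. CD96 rose by 1.50 ± 0.20 and ZAP70, a kinase of T cell receptor signalling, by an amount with a 95% interval of 0.58 to 1.41 (limma adjusted p = 0.0237 and 0.0480; 1.46 and 0.96 within the slide), whereas CD8A at 1.53 ± 0.34 (1.15 within the slide) passed adjusted over the list alone. CD3E, named in any case, was not well above background on any control, so its difference is not given, and it did not pass (limma adjusted p = 0.476). Of 21 cytotoxic lymphocyte genes, 19 were above 0, with a median of 0.73 (0.86 within the slide, camera adjusted p = 1.6e-05, adjusted p = 0.345 with an estimated correlation). It was 0.36 to 1.74 over settings, lowest with both channels well above background and highest with Agilent processed signals. The natural killer receptor KLRB1 rose by 1.65 ± 0.27 (1.11 within the slide; limma adjusted p = 0.0383). Adjusted over the list alone 8 genes were higher, among them NKG7 (1.56 ± 0.38), and HOPX, a homeodomain cofactor, was lower (-0.85 ± 0.24). Within the slide NKG7 and HOPX had 1.79 and -0.67. KLRD1 and CD160, also among the 8, were not well above background on any control.

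Myeloid genes moved in the same direction. Macrophage and dendritic cell genes were above 0 in 28 of 29 cases, with a median of 0.78 (1.12 within the slide, camera adjusted p = 4.9e-08, adjusted p = 0.436 with an estimated correlation). Over settings it was 0.53 to 1.39, and the list was not called without non-uniform spots. None passed over all genes and 10 passed adjusted over the list alone, among them CD83 (1.53 ± 0.29), LAMP3 (1.48 ± 0.30) and ITGAX (1.21 ± 0.25), with 1.53, 2.07 and 1.37 within the slide. Of 22 neutrophil genes listed 10 were tested. Among these 10, 9 were above 0, with a median of 0.71 (0.96 within the slide, camera adjusted p = 0.00085, adjusted p = 0.345 with an estimated correlation). Adjusted over the list alone 5 passed, VNN2 at 2.28 ± 0.63 (2.39 within the slide) among them. Of these 5, ALPL and MMP9 were not well above background on any control, and CXCR2 was so on 1. ALPL and MMP9 were thus kept through the patients' arrays alone. The median of the list was 0.19 without the filter on dim probes and 2.13 with Agilent processed signals. The list of inflamed epithelium and neutrophil attraction had a median of 0.58 (0.70 within the slide, camera adjusted p = 0.0093, adjusted p = 0.615 with an estimated correlation). Its genes NOS2, CXCL6, TNF and MMP12 were past the threshold adjusted over the list alone, although CXCL6 was not well above background on any control. Without CVID patient 3 the list no longer passed (0.14 to 1.32 over settings). Its median log2 ratio was -0.53 in CVID patient 2, within the controls (-0.55 to -0.36). In CVID patients 1 and 3 it was -0.019 and 0.59. Fibroblast and matrix genes had a median of 0.39 (0.59 within the slide, camera adjusted p = 0.0012, adjusted p = 0.450 with an estimated correlation; 0.28 to 0.78 over settings), and COL4A1, a basement membrane collagen, rose by 1.88 ± 0.19 (1.80 within the slide; limma adjusted p = 0.0120).

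Plasma cell genes were lower in the patients. Of 20 genes of the plasma cell and immunoglobulin list 18 were below 0, with a median of -0.80 (-0.77 within the slide, camera adjusted p = 1.9e-07, adjusted p = 0.345 with an estimated correlation). It was -1.16 to -0.52 over settings. Per biopsy the list median was -1.80, -1.21 and -1.86 in CVID patients 1, 2 and 3, against -1.04 to -0.62 in the controls. CVID patient 2 thus lay nearest to the controls, although its IGHA2 value, at -3.69, was as low as in CVID patients 1 and 3 (-3.28 and -3.71). IGHA2 passed over all genes, and 10 genes passed adjusted over the list alone. Among these were JCHAIN, which joins IgA and IgM into polymers (-1.95 ± 0.54; chromosome 4, 71521874 to 71521933), TNFRSF17, the survival receptor BCMA of plasma cells (-1.60 ± 0.48), FCRL5 (-1.14 ± 0.26) and SDC1, the surface marker CD138 (-1.04 ± 0.24). Within the slide these 4 had -2.18, -1.42, -1.07 and -0.91. The probe standing for IGHA1 had a difference of -0.57 ± 0.21 and that for IGHG1 of -0.19 ± 0.70, and neither passed (-0.78 and 0.39 within the slide). Another feature, which the files describe as the IGHA1 constant region (chromosome 14, 106174156 to 106174215), was lower by limma over all genes (-1.89 ± 0.22, -1.61 within the slide, limma adjusted p = 0.0169), as was one described as an IgA1 and IgA2 hybrid (-1.56 ± 0.18, -1.63 within the slide, limma adjusted p = 0.0167); both were singled out after their values were seen. The near-identical IGHA1 and IGHA2 can share probe signal. The list of antibody transport and mucosal B cell support was higher (median 0.26, 0.53 within the slide, camera adjusted p = 0.0096, adjusted p = 0.345 with an estimated correlation). Its members past the threshold adjusted over the list alone, the lymphoid chemokine CCL19 (1.30 ± 0.27, 1.57 within the slide), the cytokine LTB (1.01 ± 0.22, 0.86) and the homing integrin chain ITGB7 (0.97 ± 0.20, 0.84), belong to lymphocyte recruitment more than to antibody transport, and without control 3, or without the filter on dim probes, the list no longer passed (0.10 to 0.79 over settings). The B cell list did not pass (median -0.43 over 10 genes; -0.14 within the slide, camera adjusted p = 0.364), with CD79A of the B cell receptor at -0.76 ± 0.31 (-0.70 within the slide, limma adjusted p = 0.246); MS4A1, which encodes CD20, was not among the genes tested.

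Genes of absorption and metabolism were lower as lists, but not in every patient. The medians were -0.47 for lipid absorption (-0.66 within the slide, camera adjusted p = 0.0030, adjusted p = 0.633 with an estimated correlation), -0.43 for drug metabolism (-0.48, 4.5e-05, adjusted p = 0.615 with an estimated correlation) and -0.37 for fatty acid oxidation (-0.54, 0.00012, adjusted p = 0.615 with an estimated correlation). They were -0.36 for sugar, amino acid and peptide transport (-0.31 within the slide, camera adjusted p = 0.010), -0.29 for the villus tip (-0.46 and 0.0412) and -0.26 for brush border digestion (-0.50 and 0.0203), each with an adjusted p = 0.671 with an estimated correlation. Over settings these 6 were -0.69 to -0.17, -0.79 to -0.23, -0.54 to -0.13, -0.69 to 0.075, -0.67 to -0.066 and -0.71 to -0.014, and the villus tip list was not called in 10 of 27 settings. No gene of these lists was lower past the threshold over all genes. Adjusted over the list alone, the lipid synthesis enzymes MOGAT2 (-0.81 ± 0.19) and GPAM (-0.85 ± 0.19), the exporter ABCC3 (-1.13 ± 0.23) and the hydrolase EPHX1 (-0.92 ± 0.20) were lower. Within the slide they had -0.94, -0.85, -1.095 and -0.67, and a second probe of MOGAT2 gave -0.36. Against the direction of their lists, SLC6A19, the neutral amino acid transporter, was higher by 2.21 ± 0.21 (2.16 within the slide; limma adjusted p = 0.0120), and CYP1A2 (1.25 ± 0.26, 1.21 within the slide) and GGT1 (0.85 ± 0.18, 0.80) were higher adjusted over the list alone; the probes of GGT1 disagreed in sign, and another feature that the files describe as this gene, singled out after its value was seen, was higher over all genes (1.66 ± 0.25, 1.57 within the slide, limma adjusted p = 0.0293). APOA4, an apolipoprotein of chylomicrons, had a difference of -1.65 ± 0.58 (-1.53 within the slide, limma adjusted p = 0.204), which a second probe did not share.

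CVID patient 2 lay with or above the controls in most of these lists. Its median log2 ratio was 1.67 for lipid absorption and 1.92 for brush border digestion, against 1.22 to 1.63 and 1.82 to 2.04 in the controls, whereas CVID patients 1 and 3 had 0.90 and 0.39 for lipid absorption and 1.42 and 0.84 for brush border digestion. For fatty acid oxidation both CVID patient 1 (0.44) and CVID patient 2 (0.40) lay within the controls (0.26 to 0.78), and CVID patient 3 lay below them (-0.046). For the villus tip CVID patient 1 at 2.08 was close to the lowest control at 2.10, against 1.42 for CVID patient 3. Without CVID patient 3, and likewise without control 3, the lists of lipid absorption, brush border digestion, sugar, amino acid and peptide transport and the villus tip no longer passed camera, and the villus tip list was also lost without control 2. The list of drug metabolism and that of fatty acid oxidation passed without any single array. Genes expressed by all epithelial cells had a difference of -0.38 ± 0.20 (SE) in their per-array median, beside -0.26 ± 0.27 for the genes of absorption and metabolism pooled.

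Intestinal transcription factors had a median of -0.28 (-0.24 within the slide, camera adjusted p = 0.0279, adjusted p = 0.547 with an estimated correlation), a call lost in 8 of 27 settings, those without CVID patient 3 or control 3 among them (-0.35 to -0.045 over settings). GATA4, which specifies proximal intestine (chromosome 8, 11617080 to 11617139), had a difference of -0.72 ± 0.17 and NR1H3, the sterol receptor LXR alpha, of -0.83 ± 0.17; both passed adjusted over the list alone but not over all genes (limma adjusted p = 0.0936 and 0.0654; -0.76 and -0.79 within the slide). Oxidative phosphorylation genes had a median of -0.11, which turned to 0.095 with median centring (-0.23 within the slide, camera adjusted p = 0.0388), and cell cycle genes of 0.27 (0.24 within the slide, camera adjusted p = 0.0412), each with an adjusted p = 0.671 with an estimated correlation. Without CVID patient 3 both calls were lost; the first was also lost without CVID patient 2, control 2 or control 3, and the second without CVID patient 1 or control 1. In all, oxidative phosphorylation was not called in 12 and the cell cycle in 14 of 27 settings (-0.23 to 0.095 and 0.14 to 0.44 over settings). The cell cycle list did not pass within the shared slide either (camera adjusted p = 0.287, with the spread taken from the patients alone).

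**Figure D3:**
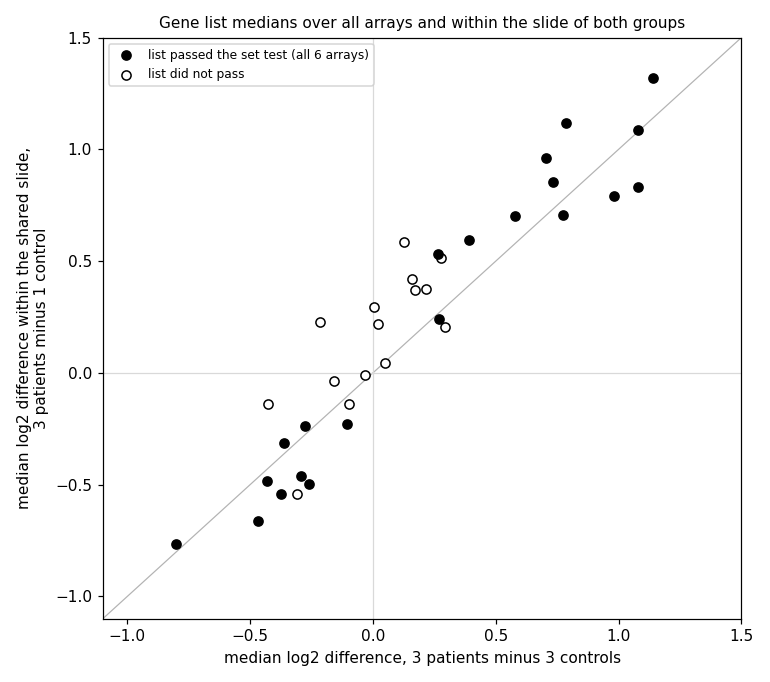
Median log2 difference of each of the 36 gene lists over all arrays (x axis, 3 patients minus 3 controls) against that within the shared slide (y axis, 3 patients minus 1 control); filled points passed the camera test and the line marks equal values. The interferon gamma list lies at 1.14 and 1.32, and the plasma cell list at -0.80 and -0.77.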

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

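Chosen after seeing the data were the comparison within the shared slide, slide as a random block, leaving out non-uniform spots, and both other treatments of marked local backgrounds. Against 201 genes higher and 16 lower, Agilent processed signals gave 258 and 9, scaling between arrays 101 and 9, Cy5 alone 17 and 1, no filter on dim probes 107 and 10, both channels well above background 128 and 14, robust eBayes 93 and 7, array quality weights 353 and 59, and an adjusted p of 0.10 552 and 119. Median centring, the authors' table, scan as a block and the shared slide alone each gave 0 and 0, with smallest adjusted p of 0.0569, 0.0713, 0.0643 and 0.144. Marked backgrounds kept as given left 3 and 0, where the ratios of CVID patient 2 had a median absolute deviation of 0.031, and leaving out those spots gave 195 and 18. Leaving out non-uniform spots gave 134 and 7, and slide as a random block (consensus correlation 0.317) 145 and 13. Without 1 array the counts ranged from 0 to 138 higher and from 0 to 27 lower. Apart from the fewer arrays or genes, the cause of these changes was not tested. All called genes listed differed without overlap between the groups, so leaving out arrays or controls cannot turn their sign. Of those with a value, 212 of 213 kept it in the authors' table and 127 of 130 without non-uniform spots. Median centring moved the median of all genes from 0.0098 to 0.16, and its unadjusted calls to 1487 higher and 192 lower from 2092 and 1224; the median of oxidative phosphorylation, at -0.11, was 0.095 there.

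With the replicate block, 40 genes were higher and 4 lower, and 19 lists passed. Same-numbered arrays did not deviate together (r = -0.0016, -0.059 and -0.050 across genes), so the numbers do not pair the biopsies.

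The number of lists past the threshold was 21, and 0 with estimated correlations, 3 by fry and 4 without non-uniform spots. In every other setting it was between 14 and 25. Leaving out non-uniform spots removes most bright spots. There 4 of the 21 lists passed, 13 did not, and the others had too few genes left to be tested. The test of no list that passed changed direction. Yet without non-uniform spots the medians of oxidative phosphorylation and of sugar, amino acid and peptide transport were 0.054 and 0.075. Among the single genes reported, those that changed sign had not passed over all genes. HBD, at -0.11, was 0.24 with Agilent processed signals, 0.15 with median centring, 0.36 with scaling, 0.045 with scan as a block and within the slide, 0.094 without control 2, 0.041 without CVID patient 3 (-0.31 to 0.094 over the arrays left out) and 0.43 with marked backgrounds as given. KLK1, at -0.58, was 0.0072 with scan as a block and within the slide, and HBB, at 0.070, was -0.026 without control 1 (-0.026 to 0.23 over the arrays left out). UCHL1 was 0.11 with scaling, DNAJB9 0.042 with Cy5 alone and NEFL -0.17 without the filter. BCL11A was 0.023 as a mean over probes and 0.52 without non-uniform spots, where APOA4 was 0.053. DEFB1 and TAC1 were 0.017 and 0.19 with marked backgrounds as given. Signal limits the result in controls 1 and 2, the arrays with the fewest probes above background; 23 of the 201 higher genes were not well above background on any control.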

Other observations

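The tests of the slide, of the gap between T cell and plasma cell genes and of antibody transcripts were chosen after the results were seen, and the genes of the next paragraph were named after their values were seen.

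Some genes called higher lay outside the fixed lists, and those named here form no tested group. GPR18 and GPR171, orphan receptors of lymphoid cells, were higher by 2.11 ± 0.25 and 2.09 ± 0.34 (limma adjusted p = 0.0181 and 0.0377; 1.94 and 1.69 within the shared slide). The adaptor HCST, which carries signals of activating receptors, and FYB1, an adaptor of T cell adhesion, were higher by 1.56 ± 0.18 and 1.77 ± 0.30 (limma adjusted p = 0.0169 and 0.0411; 1.60 and 1.62 within the slide). FCRL4, a receptor of tissue memory B cells, was higher by 2.29 ± 0.39 (2.42 within the slide, limma adjusted p = 0.0404), opposite in sign to FCRL5 of plasma cells at -1.14 ± 0.26. TRIM22, an interferon-induced antiviral protein, the complement protein C2 and SERPINA1, which inhibits neutrophil elastase, were higher by 1.93, 1.86 and 1.36, and by 2.12, 2.19 and 1.35 within the slide. MAGEC1, a testis antigen, was also called, at 2.05 ± 0.19 (2.07 within the slide, limma adjusted p = 0.0120). Of the 201 genes called higher, 80 carried only an accession, clone or probe identifier, and 132 (65.7%) were well above background on all arrays, against 72.7% of the genes tested.

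Lists that did not pass were measured too. Camera adjusted p was 0.720 for Paneth cells (median difference 0.020) and for goblet cells (0.13), 0.695 for enteroendocrine cells (0.17), 0.483 for crypt stem cells (-0.16), 0.126 for smooth muscle (0.16), 0.208 for endothelium (0.30), 0.428 for mast cells and eosinophils (0.22) and 0.905 for red blood cells (0.047). It was 0.168 for sterol synthesis (0.28), 0.222 for iron, vitamin and mineral absorption (-0.31), 0.175 for immediate early and heat shock genes (-0.22, but 0.23 within the shared slide) and 0.222 for the unfolded protein response (-0.097). For Brunner's gland and gastric mucosa (0.0046; 0.556) the median differed in sign from mean and test, as for enteric neurons and glia (-0.033; 0.905). Adjusted over the list alone, PLN of smooth muscle, NEFL of neurons and CCR3 of eosinophils were among the genes past the threshold, although NEFL was not well above background on any control. Within the shared slide, sterol synthesis (0.51), goblet (0.59), enteroendocrine (0.37) and smooth muscle (0.42) lists and that of iron, vitamin and mineral absorption (-0.54) had larger medians and passed camera (adjusted p = 0.00027, 0.0075, 0.0020, 0.00027 and 0.0035). These calls rest on 1 control and take the spread from the patients alone, so a peculiarity of control 3 is not excluded.

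Slide and scan were weighed as a source of the list differences. Within the slide that held both groups, 21 of 21 lists kept their direction and at least 0.5 of their median. That comparison reuses 4 of the 6 arrays, so part of this is built in, and it held 1 control, so a peculiarity of control 3 and the disease cannot be told apart there.

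Of the 10 splits of the 6 arrays into 3 and 3, 3 gave at least as many lists as the real one (21; highest other 23), and both others put CVID patients 1 and 3 on the same side, apart from CVID patient 2. For genes, 1 of 10 splits, the real one, called as many as 201 higher or 16 lower (highest other 0; limma, 3316 unadjusted against at most 1089). With 10 splits no share under 0.05 can be reached.

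A smaller epithelial share is a candidate explanation of the lower absorption and metabolism lists. Genes of all epithelial cells differed by -0.385 (SE 0.204), past the bound of -0.128 that this explanation needs. The rule behind the bound, a share of 0.5, was set beforehand. The bound itself came from these data, as that share of the pooled difference of absorption and metabolism genes (-0.256, SE 0.271). That pooled difference was smaller than its SE, and no interval was taken for either difference. An earlier version of the epithelial value was seen before the background repair. Of the 19 genes of all epithelial cells 5 were above 0, EPCAM (0.19 ± 0.28) and CDH1 (0.17 ± 0.21) among them, so the support is uneven. A change of the epithelium in CVID itself, or a different sampling site or depth, was not tested.

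T cell and macrophage lists were higher while the plasma cell list was lower. A smaller epithelial share alone would raise all other cell types alike, whereas these lists differed in direction. The T cell minus plasma cell gap was 1.57 (SE 0.366, 95% t interval 0.554 to 2.59). Both the pair of lists and the interval rule were set after earlier values were seen. The gap therefore restates the pattern, and its interval is no separate test of this explanation. Whether fewer antibody transcripts were the whole cause was not settled. Plasma cell genes encoding no antibody chain differed by -0.555 (SE 0.198, 95% t interval -1.104 to -0.0057), and 12 of 14 were below 0. SDC1, whose cell of origin was not tested, was among these 14. The rule that this interval lie below 0 was met narrowly, and it was set after the value was seen. An earlier rule asked for 0.5 of the fall of the whole list by more than 1 SE. Under it, -0.357 did not reach -0.380, so no verdict is drawn. Slide, sampling and cell content remain open, and a loss of plasma cells in CVID was not tested.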
